A study of Rattus norvegicus with 6 samples.

How the data were processed

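Tendon RNA from Sprague-Dawley rats was measured on 6 arrays, 1 array per sample, 3 after control surgery and 3 after tendon injury. Tendons were taken 1 week after surgery, per the labels' protocols, and rats were assigned to surgery or injury at random. The labels call the replicates biological, and each was treated as 1 sample of its group. Sex of the rats, which tendon was cut and how are not given in the sources used here. The titles of the samples name a rat transcriptome array, while the protocol names a mouse array of the same maker. The probe sets are named for rat genes in the platform annotation, so the values were read as those of a rat array. RNA was extracted with a phenol reagent and cleaned on columns, and biotin-labelled complementary RNA was hybridised, per the labels' protocols.

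The deposited table holds 1 log2 signal per probe set and array for 68842 probe sets. The authors made these log2 values with Affymetrix Expression Console, per the submitters' processing notes, with a version, a background correction, a summarisation and a normalization that are not given in the sources used here. The log2 unit was read from the values, which have a shared upper end near 19.9 on all 6 arrays. The arrays did not share 1 distribution, so no quantile normalization across arrays is visible in the values. Values within 0.02 of an array's highest value were treated as at its ceiling. No fold is given for a gene at the ceiling on arrays of both groups. No detection p-values were used here, so no probe set was called absent. Arrays have no read depth, and the number of arrays limits the precision.

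Names came from the platform annotation. It gave 1 gene symbol to 23446 probe sets, several to 505 and none to 44891, which are unnamed here and not without a gene. Entrez identifiers of 22077 probe sets with 1 symbol were matched to a reference table of rat genes on assembly GRCr8, which changed 1 symbol. No coordinates are printed. Each gene was represented by the probe set with the highest mean over the 6 arrays among those naming that gene alone, a choice that mattered for the 1182 genes with more than 1 probe set, and 22093 genes were tested.

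Values were used as deposited, with no further normalization and no filter on dim probe sets. Injured tendon was compared with control tendon in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on the log2 values, a two-sided test and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05, and calls of at least 2-fold were counted beside it. Differences are injured minus control on the log2 scale, errors of differences are standard errors (SE), and group means are given with the standard deviation (SD) over 3 arrays. A difference given for a single array is against the control mean. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1 and was not used for single genes.

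Gene lists were chosen before the data were examined, as were the comparison, the test, the first set of alternatives and the rule for named genes. There were 16 lists of processes and 16 lists of cell type markers, with 501 genes, of which 476 were measured, 8 of them through an older symbol. Each list was tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 32 lists. Camera compares the genes of a list with all other genes. Each call was repeated with the correlation estimated for the list, and with fry, which asks whether the genes of a list move on balance in 1 direction. The genes past the test were counted over all genes and adjusted over the list alone.

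The rule for named genes took the 6 largest differences in each direction among genes past the threshold, and from every list the 2 largest differences past the threshold, filled up with the genes of highest mean signal. No gene passed, so the rule gave the 2 genes of highest mean signal in each list. Other genes are named as chosen after their values were seen, among them the 10 largest differences in each direction at an unadjusted p under 0.05 that met the other conditions of the rule.

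The scripts were tested on simulated data. With the spread measured within both groups, the test across 22093 genes recovered 10% of 50 genes changed by a log2 of 1, 46% of those changed by 2, 70% of those changed by 4 and 96% of those changed by 8. With the spread of the control group alone these shares were 54%, 74%, 88% and 98%. The changes were put on genes drawn at random, with noise independent between genes. These shares need not hold for genes with a wide spread between arrays. A lack of calls therefore does not show that large changes are absent. In 100 simulated sets of unchanged groups that kept the correlation between genes seen on these arrays, camera with the preset correlation called a median of 13 of the 32 lists and at most 21, and camera with an estimated correlation called 0.

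Alternatives were quantile normalization over all probe sets, centring of each array on its median, leaving out dim genes, the mean of a gene's probe sets, every probe set tested, eBayes with trend and robust, array quality weights, the replicate number as a block, each array left out in turn, and lists without genes that several lists share. Further alternatives chosen after the data were seen were the 3 control arrays against injured replicate 1 alone, with the preset and with an estimated correlation, the median of the unnamed probe sets as a covariate, and leaving out genes at the ceiling. The covariate was 6.61 and 6.50 on injured replicates 2 and 3 and 5.49 to 5.79 on the other arrays. The group difference it leaves rests chiefly on injured replicate 1, so this setting cannot separate background from injury.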

Results

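Gene expression was measured in rat tendon 1 week after control surgery (3 arrays) or tendon injury (3 arrays). The median log2 signal over all probe sets was 5.70, 5.79 and 5.99 on control replicates 1, 2 and 3 and 5.79, 6.68 and 6.59 on injured replicates 1, 2 and 3. Across genes, the control arrays correlated with one another at r = 0.960 to 0.986. Injured replicate 1 correlated with the control arrays at r = 0.951 to 0.966, with injured replicate 2 at r = 0.728 and with injured replicate 3 at r = 0.790, while injured replicates 2 and 3 correlated at r = 0.965. Genes are not independent replicates, so these values describe the arrays only. The first principal component held 82.9% of the variance and set injured replicates 2 and 3 apart from the other 4 arrays. The design implies 1 comparison, which asks how the transcripts of tendon differ 1 week after injury from those after control surgery.

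Injured tendon had lower signals of the genes that make tendon matrix. The list of tenocyte transcription factors and tendon matrix was lower, with a median log2 difference of -3.01 over 17 genes (camera adjusted p = 2.66e-12; adjusted p = 0.359 with an estimated correlation). All 17 differences were below 0, and the list's median was below the control mean on every injured array, by -1.94, -3.20 and -2.93 on replicates 1, 2 and 3. The reference genes on these arrays were at -0.30, -2.46 and -2.11. Of these genes, 13 of 17 passed adjusted over the list alone and 0 passed over all genes tested. Kera and Tnmd were chosen after their values were seen. Kera (probe set TC0700000581.rn.1), which encodes the small leucine-rich proteoglycan keratocan, had a log2 signal of 17.18 ± 1.87 (SD, n = 3) in control tendon and 9.35 ± 0.45 (SD, n = 3) in injured tendon, a difference of -7.83 (SE 0.94), or 228-fold, with a limma adjusted p of 0.317. Tnmd (TC0X00000867.rn.1), which encodes tenomodulin, a membrane protein typical of mature tenocytes, was at 12.94 ± 1.83 in control and 5.93 ± 1.18 in injured tendon (SD, n = 3), a difference of -7.01 (SE 1.06, adjusted p = 0.322). It read 4.93 and 5.62 on injured replicates 2 and 3, below the median unnamed probe set of those arrays (6.61 and 6.50), so the size of its difference is limited by background.

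Other genes of the tendon list went the same way. Ogn, which encodes the proteoglycan osteoglycin, differed by -7.14 (SE 1.71), with -3.31 on injured replicate 1 against the control mean. Prg4, which, like Ogn, was named by the rule and encodes the lubricating protein lubricin, differed by -1.54 (SE 0.55). Among other genes of this list chosen after their values were seen, Chad (chondroadherin) differed by -7.64 (SE 1.66), Comp (cartilage oligomeric matrix protein) by -5.68 (SE 1.13), Thbs4 (thrombospondin 4) by -4.57 (SE 1.41) and Cilp (cartilage intermediate layer protein) by -3.01 (SE 0.29). Cilp read between 9.45 and 10.36 on the control arrays and between 6.56 and 6.85 on the injured arrays, and its adjusted p was 0.217. None of these genes passed the threshold over all genes.

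Collagen genes were lower as well. The list of fibrillar and FACIT collagens had a median difference of -1.36 over 16 genes (camera adjusted p = 5.35e-10; adjusted p = 0.359 with an estimated correlation), and 11 of 16 genes passed adjusted over the list alone. The medians on injured replicates 1, 2 and 3 were -1.43, -1.47 and -1.13. The reference genes were at -0.30, -2.46 and -2.11 there, so on injured replicates 2 and 3 the collagen list fell less than the reference genes. Col1a1 and Col1a2, which encode the chains of type I collagen, the main fibre of tendon, differed by -5.90 (SE 1.11) and -6.95 (SE 1.03). Col1a2 was at 16.27 ± 1.83 in control and 9.32 ± 1.07 in injured tendon (SD, n = 3), and its adjusted p was 0.322. Col3a1, a collagen gene associated with early scar, was chosen after its values were seen and differed by -3.36 (SE 1.05).

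The enzymes that hydroxylate, fold and cross-link collagen followed the collagens. Their list had a median of -0.79 over 19 genes (camera adjusted p = 9.60e-10; adjusted p = 0.359 with an estimated correlation), all 19 differences lay below 0 and 5 of 19 genes passed adjusted over the list alone. The list was at -0.86, -0.82 and -0.64 on injured replicates 1, 2 and 3. The reference genes were at -0.30, -2.46 and -2.11, lower than the enzymes on replicates 2 and 3. P4ha1, a prolyl hydroxylase subunit, differed by -1.26 (SE 0.27) and Plod2, a lysyl hydroxylase, by -1.72 (SE 0.80). Matricellular and provisional matrix genes had a median of -2.34 over 18 genes (camera adjusted p = 1.42e-05; adjusted p = 0.359 with an estimated correlation), with 1 gene past the test adjusted over the list alone. Sparc, which encodes a collagen-binding matrix protein, differed by -4.28 (SE 1.24). Dcn, which encodes decorin, was at the ceiling on all 3 control arrays and on injured replicate 1, so its difference of -1.71 is limited by the ceiling and no fold is given. Matrix-degrading proteases and their inhibitors were not called (median 0.11, mean -0.34, camera adjusted p = 0.579). The median and the mean of that list differ in sign, camera put it lower and fry put it higher, and its median was -0.35 after quantile normalization and -0.42 after centring. Mmp2, a gelatinase, differed by -3.62 (SE 0.73) and Timp3, a protease inhibitor, by -4.87 (SE 2.10). Timp3 was at the control level on injured replicate 1, 0.06 from the control mean, against -7.00 and -7.67 on injured replicates 2 and 3.

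**Figure D1:**
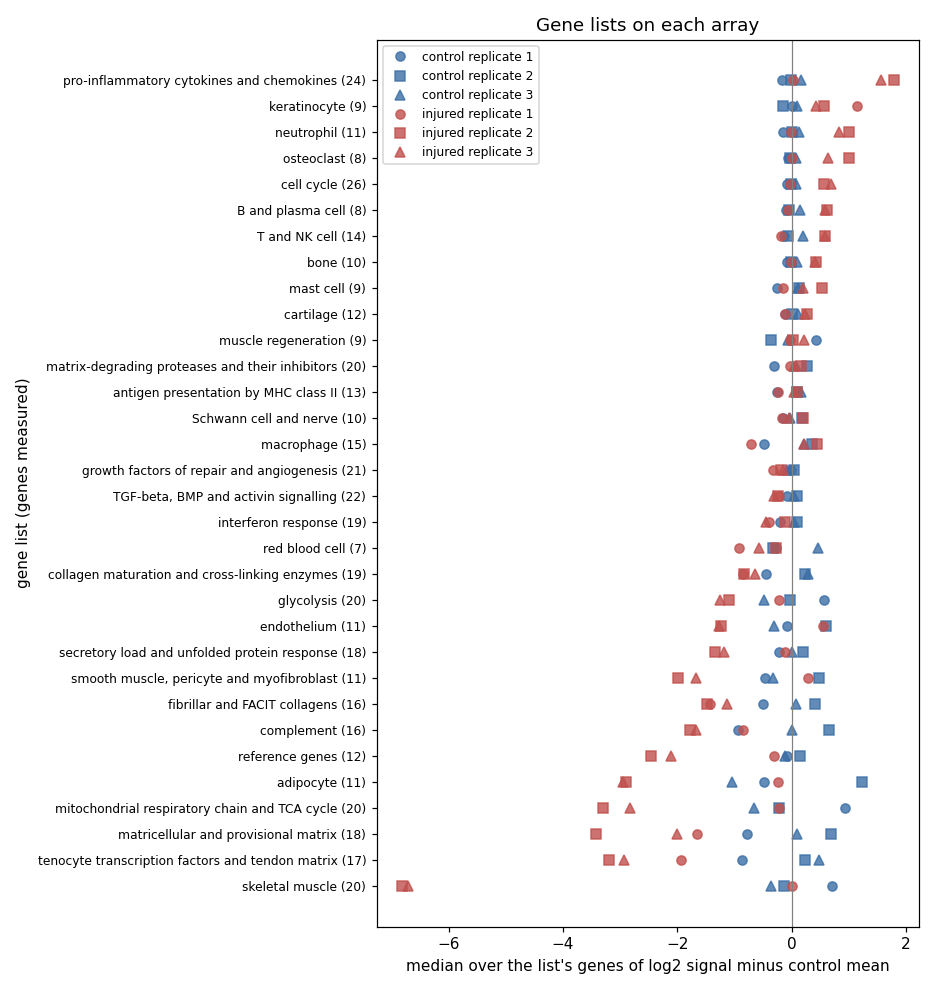
Median over the genes of each list of the log2 signal minus the control mean, 1 point per array, for the 32 lists, with the number of measured genes in parentheses. The tendon list lies at -1.94, -3.20 and -2.93 on injured replicates 1, 2 and 3, while the skeletal muscle list lies at 0.00, -6.82 and -6.72.

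Lists of signalling, complement and interferon response were also lower, but the medians of complement and interferon response overlapped between injured and control arrays. Complement was at -0.94 on control replicate 1 and at -0.855, -1.77 and -1.67 on injured replicates 1, 2 and 3. Interferon response was at -0.20 on control replicate 1 and at -0.40, -0.12 and -0.44. TGF-beta signalling was at -0.22, -0.24 and -0.30 on the injured arrays, and growth factors were at -0.33, -0.19 and -0.15. The reference genes were at -0.30, -2.46 and -2.11. TGF-beta, BMP and activin signalling had a median of -0.35 over 22 genes (camera adjusted p = 8.85e-05; adjusted p = 0.359 with an estimated correlation), with 2 genes past the test adjusted over the list alone. Chrdl1, which encodes a BMP antagonist, differed by -4.48 (SE 0.72), and Tgfbr1, a TGF-beta receptor gene, by -1.38 (SE 0.68), with 0.14 on injured replicate 1 and -2.15 and -2.12 on injured replicates 2 and 3 against the control mean. Growth factors of repair and angiogenesis had a median of -0.12 over 21 genes (camera adjusted p = 0.00256; adjusted p = 0.359 with an estimated correlation; 0.0754 with the median of the unnamed probe sets as a covariate), and 0 passed adjusted over the list alone. The covariate leaves chiefly injured replicate 1, so its result does not tell background from injury. In that list, Igf1 differed by -2.94 (SE 0.62) and Fgf7 by -1.19 (SE 0.44). Complement genes had a median of -1.48 over 16 genes (camera adjusted p = 1.29e-04; adjusted p = 0.359 with an estimated correlation), 3 of them past the test adjusted over the list alone. C7, a component of the membrane attack complex, differed by -3.96 (SE 0.76), and Serping1, the C1 inhibitor gene, by -4.75 (SE 1.59), with -1.59, -6.31 and -6.35 on the injured arrays. Serping1 read 11.35 on injured replicate 1, above its 10.86 on control replicate 1. Interferon response genes had a median of -0.38 over 19 genes (camera adjusted p = 6.04e-04; adjusted p = 0.359 with an estimated correlation), 4 of them past the test adjusted over the list alone, with Gbp2 at -1.91 (SE 0.50) and Ifit1 at -1.45 (SE 0.46). Without injured replicate 1 the interferon list had an adjusted p of 0.0544.

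Secretory and metabolic lists were lower chiefly on injured replicates 2 and 3. Secretory load and unfolded protein response had a median of -1.03 over 18 genes (camera adjusted p = 1.49e-05; adjusted p = 0.359 with an estimated correlation), with 4 genes past the test adjusted over the list alone, and array medians of -0.11, -1.33 and -1.18 on injured replicates 1, 2 and 3. Hsp90b1, an endoplasmic reticulum chaperone gene, differed by -0.85 (SE 0.34), and Xbp1, a transcription factor of the unfolded protein response, by -1.81 (SE 1.03), with 0.53, -2.39 and -3.55 on the injured arrays. Glycolysis genes had a median of -0.80 over 20 genes (camera adjusted p = 3.28e-05; adjusted p = 0.359 with an estimated correlation), 1 of them past the test adjusted over the list alone. Gpi differed by -3.25 (SE 1.27), with -0.49 on injured replicate 1, and Gapdh was at the ceiling on all 6 arrays. Mitochondrial respiratory chain and TCA cycle genes had a median of -2.25 over 20 genes (camera adjusted p = 1.03e-09; adjusted p = 0.421 with an estimated correlation), with array medians of -0.23, -3.30 and -2.83 and 0 genes past the test adjusted over the list alone. Cox6a2, a muscle form of a respiratory chain subunit, differed by -4.66 (SE 2.29), with 0.26 on injured replicate 1, and Cycs, cytochrome c, by -2.37 (SE 0.82). The reference genes, often used as internal standards, had a median of -1.54 over 12 genes (camera adjusted p = 1.42e-05; adjusted p = 0.359 with an estimated correlation), 0 past the test adjusted over the list alone, and array medians of -0.30, -2.46 and -2.11. B2m differed by -2.02 (SE 0.74), with -0.39 on injured replicate 1, and Pgk1 by -2.55 (SE 0.79). With the median of the unnamed probe sets as a covariate, none of these 4 lists was called (adjusted p = 0.163 for secretory load, 0.0574 for glycolysis, 0.0695 for mitochondria and 0.395 for reference genes). The covariate leaves chiefly the difference of injured replicate 1, where these lists were lowered least, so this does not tell background from injury.

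Genes of inflammation were higher on injured replicates 2 and 3 and near the control level on injured replicate 1. Pro-inflammatory cytokines and chemokines had a median of 1.06 over 24 genes (camera adjusted p = 0.00175; adjusted p = 0.650 with an estimated correlation), with array medians of 0.02, 1.79 and 1.56 on injured replicates 1, 2 and 3, and 0 genes past the test adjusted over the list alone. Ccl3, a chemokine gene of activated macrophages, was at 5.93 ± 0.23 in control tendon and 12.99 ± 5.50 in injured tendon (SD, n = 3), a difference of 7.06 (SE 2.67, adjusted p = 0.322), and read 6.84, 17.45 and 14.69 on the injured arrays. Ccl2, a monocyte chemoattractant gene, differed by 1.82 (SE 1.36), with -0.98, 3.85 and 2.59 on the injured arrays. Chosen after their values were seen, Cxcl2, a neutrophil chemoattractant gene, differed by 5.69 (SE 2.39) and Il1b by 4.62 (SE 2.12). Both read close to control on injured replicate 1, at 5.50 for Cxcl2 and 6.05 for Il1b. Olfactory and vomeronasal receptor genes, 1276 in number, were 2.11 and 2.03 above the control mean on injured replicates 2 and 3, more than this list. With the median of the unnamed probe sets as a covariate the list had a median of 0.08 and no call (adjusted p = 0.988), and camera turned its direction. What the covariate leaves rests chiefly on injured replicate 1, where the list was at 0.02, so this does not tell background from injury.

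Neutrophil markers had a median of 0.57 over 11 genes (camera adjusted p = 0.0124; adjusted p = 0.650 with an estimated correlation), with array medians of -0.02, 1.01 and 0.82 and 0 genes past the test adjusted over the list alone. Cxcr2, a chemokine receptor gene, differed by 1.30 (SE 0.80), with -0.32 on injured replicate 1, and Lcn2 by 0.86 (SE 0.54), and S100a9, chosen after its values were seen, by 2.75 (SE 1.17), with 0.33 on injured replicate 1. Cell cycle genes had a median of 0.42 over 26 genes (camera adjusted p = 0.0221; adjusted p = 0.722 with an estimated correlation), with array medians of -0.02, 0.56 and 0.69 and 0 genes past the test adjusted over the list alone. The median of that list was -0.07 after quantile normalization and -0.11 after centring on array medians, with no call at either setting, and without injured replicate 3 its adjusted p was 0.107. With dim genes left out its camera adjusted p was 0.0571. Of its 26 genes, 22 differed above 0 and 4 below. Its brightest genes, Mcm4 and Tyms, were among those below, at -0.26 (SE 0.15) and -0.32 (SE 0.26). Mki67 and Top2a, chosen after their values were seen, differed by 1.09 (SE 0.56) and 1.03 (SE 0.50). Both lists were less far above the control mean on injured replicates 2 and 3 than the receptor genes, and with the covariate neither was called (adjusted p = 0.966 for neutrophil markers, with a median of -0.02 and a turned direction, and 0.992 for the cell cycle). Here too the covariate leaves chiefly injured replicate 1, where both lists were at -0.02, and does not tell background from injury.

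Macrophage markers were not called (median -0.10 over 15 genes, camera adjusted p = 0.206), with array medians of -0.72, 0.44 and 0.22. Gpnmb differed by -0.35 (SE 0.54) and Mrc1, a receptor gene of resident macrophages, by -1.59 (SE 0.51). Antigen presentation by MHC class II was not called (median 0.04, mean -0.36, camera adjusted p = 0.109), although 2 of 13 genes were lower adjusted over the list alone. Without control replicate 1 the macrophage list had an adjusted p of 0.00341 and the class II list of 0.00294, both lower, and without injured replicate 2 these values were 0.0352 and 0.0217. With the covariate, which leaves chiefly the difference of injured replicate 1, camera called both lower (adjusted p = 8.04e-05 and 6.51e-04). RT1-Da, a class II chain gene, differed by -2.65 (SE 0.56) and Ctss, the cathepsin S gene, by -1.12 (SE 0.36). That list had a median of -0.44 after quantile normalization, with an adjusted p of 0.00399, of -0.49 after centring, with an adjusted p of 0.00661, and an adjusted p of 0.0328 without injured replicate 3. Osteoclast markers (median 0.55, adjusted p = 0.579), T and NK cell markers (0.34, 0.109), B and plasma cell markers (0.41, 0.0548) and mast cell markers (0.18, 0.737) were not called by camera. Without injured replicate 1 the T and NK cell list had an adjusted p of 0.0440, and without control replicate 3 of 0.0463, both higher. With a trend in the variance, camera called the B and plasma cell list higher (adjusted p = 0.0457). The medians of the T and NK cell, B and plasma cell and mast cell lists lay below 0 after quantile normalization, at -0.19, -0.09 and -0.31, and after centring, at -0.19, -0.12 and -0.35. The osteoclast gene Ctsk, which encodes cathepsin K, differed by -2.16 (SE 0.49), and Nfatc1 by -0.47 (SE 0.38). Cd4 and Cd3d differed by -1.17 (SE 0.34) and 0.22 (SE 0.29), Fcrla and Cd79a by 0.86 (SE 0.46) and 0.17 (SE 0.17), and the mast cell genes Cpa3 and Kit by -1.40 (SE 0.45) and 0.11 (SE 0.21).

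Markers of neighbouring tissues separated the injured arrays from one another. Skeletal muscle markers had a median of -4.32 over 20 genes (camera adjusted p = 1.46e-08; adjusted p = 0.421 with an estimated correlation), with 0.00, -6.82 and -6.72 on injured replicates 1, 2 and 3 and 0 genes past the test adjusted over the list alone. Acta1, skeletal actin, was at the ceiling on all control arrays and on injured replicates 1 and 3, so no fold is given, and it read 14.38 on injured replicate 2. Neb, the nebulin gene, differed by -2.12 (SE 1.51), with 0.22, -5.62 and -0.95 on the injured arrays. Ckm, the muscle creatine kinase gene, chosen after its values were seen, read 18.15 on injured replicate 1 and 9.91 and 10.72 on injured replicates 2 and 3, against 17.80 ± 0.78 (SD, n = 3) in control tendon. Adipocyte markers had a median of -1.96 over 11 genes (camera adjusted p = 1.75e-04; adjusted p = 0.453 with an estimated correlation), with array medians of -0.23, -2.90 and -2.95, and Fabp4 and Lpl differed by -4.46 (SE 2.62) and -5.62 (SE 2.06), with 1.57 and -1.25 on injured replicate 1. With the covariate neither list was called, with medians of -0.31 for skeletal muscle (adjusted p = 0.142) and -0.22 for adipocytes (adjusted p = 0.966). What it leaves rests chiefly on injured replicate 1, where the lists were at 0.00 and -0.23. The covariate thus does not tell background from injury here.

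Vessel markers were split in the same way. Endothelial markers had a median of -0.82 over 11 genes (camera adjusted p = 0.00596; adjusted p = 0.650 with an estimated correlation), with 0.55, -1.23 and -1.26 on injured replicates 1, 2 and 3. Emcn, the endomucin gene, differed by -2.53 (SE 0.73) and Pecam1 by -2.32 (SE 1.76), with 1.77 for Pecam1 on injured replicate 1. Smooth muscle, pericyte and myofibroblast markers had a median of -1.13 over 11 genes (camera adjusted p = 0.00192; adjusted p = 0.517 with an estimated correlation), with array medians of 0.29, -1.99 and -1.67. Des, the desmin gene, differed by -2.50 (SE 1.91), with 0.70 on injured replicate 1, and Rgs5, a pericyte gene, by -6.53 (SE 1.74), with -2.65 on injured replicate 1. Camera called neither list after quantile normalization, with adjusted p of 0.127 for endothelium and 0.0604 for smooth muscle, although the medians were then -1.22 and -1.44. It also called neither after centring (adjusted p = 0.175 and 0.0805) or with dim genes left out (0.132 and 0.0644). With the covariate neither was called, with medians of 0.48 (adjusted p = 0.0773, direction turned) and 0.09 (adjusted p = 0.966, put lower by camera). These medians rest chiefly on injured replicate 1, at 0.55 and 0.29, and do not tell background from injury. In the adipocyte, endothelial and smooth muscle lists 0 genes passed adjusted over the list alone.

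Keratinocyte markers were higher, with a median of 0.98 over 9 genes (camera adjusted p = 0.0106; adjusted p = 0.359 with an estimated correlation), array medians of 1.14, 0.57 and 0.42 and 0 genes past the test adjusted over the list alone. The receptor genes were further above the control mean on injured replicates 2 and 3, at 2.11 and 2.03. The rise of the keratinocyte list on those arrays therefore cannot be told from background. Krt1, a keratin of the upper epidermis, read 14.04 on injured replicate 1, 5.75 and 5.61 on injured replicates 2 and 3 and 5.19 ± 0.19 (SD, n = 3) in control tendon. Krt10, its partner, read 10.38, 6.57 and 6.53 on the injured arrays. The keratinocyte list had an adjusted p of 0.0916 without injured replicate 1. Red blood cell markers were lower, with a median of -0.65 over 7 genes (camera adjusted p = 0.0260; adjusted p = 0.478 with an estimated correlation) and 0 past the test adjusted over the list alone. The list was at -0.92, -0.28 and -0.57 on injured replicates 1, 2 and 3 and at -0.27, -0.32 and 0.47 on control replicates 1, 2 and 3. The globin genes Hba-a1 and Hbb-b1 differed by -3.53 (SE 1.16) and -3.99 (SE 1.19), while 2 of the 7 genes differed above 0. Without injured replicate 1 the red blood cell list had an adjusted p of 0.151, and without control replicate 3 of 0.0902.

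Muscle regeneration (median 0.15, mean -0.20, camera adjusted p = 0.737), cartilage (0.17, -0.13, 0.737), bone (0.26, 0.28, 0.123) and Schwann cell and nerve markers (-0.04, -0.19, 0.196) were not called. The medians of the muscle regeneration, cartilage and bone lists were -0.34, -0.34 and -0.20 after quantile normalization, and after it cartilage had an adjusted p of 0.0445. With the covariate, which leaves chiefly the difference of injured replicate 1, the nerve list was called lower (adjusted p = 0.0482). Myh3 and Myh8, the developmental myosins of muscle regeneration, differed by -2.01 (SE 0.61) and -1.40 (SE 0.70), with 0.05 for Myh8 on injured replicate 1. Ucma and Sox9 of the cartilage list differed by -1.96 (SE 0.92) and -0.14 (SE 0.16), the bone genes Ibsp and Sp7 by 0.29 (SE 0.30) and 0.34 (SE 0.18), and the nerve sheath genes Pmp22 and Ncmap by -1.59 (SE 0.58) and -0.06 (SE 0.25).

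Among other genes chosen after their values were seen, Mt1 and Mt1f, which encode metal-binding metallothioneins, were above the highest control array on every injured array. Mt1 was at 11.45 ± 1.30 in control and 15.59 ± 2.64 in injured tendon (SD, n = 3), a difference of 4.14 (SE 1.43, adjusted p = 0.322), and read 18.54 on injured replicate 1. Mt1f differed by 3.02 (SE 1.12), with 5.58, 1.94 and 1.56 on the injured arrays. Without injured replicate 1 the differences were 2.66 for Mt1 and 1.75 for Mt1f. Il1rn, the interleukin 1 receptor antagonist gene, differed by 3.14 (SE 1.11) and Clec4d, a lectin receptor gene of myeloid cells, by 4.43 (SE 1.63). On injured replicate 1 these genes were only 0.62 and 0.87 above the control mean, and without that array the differences were 4.40 and 6.21. Mylk4, a kinase gene of striated muscle, read 6.14, 6.68 and 6.57 on the injured arrays and 14.58 ± 2.27 (SD, n = 3) in control tendon. The largest differences at an unadjusted p under 0.05 also held Clec3a (-8.40, SE 2.88), Adipoq (-6.71, SE 1.68) and Itgbl1 (-6.48, SE 1.42), all lower. Among the higher genes were Edaradd (3.76, SE 1.51; 1.60 with the mean of its probe sets and 5.28 without injured replicate 1), Eloa2l-ps1 (2.87, SE 1.12), Kplce (2.81, SE 0.71), the olfactory receptor gene Or14j3b (2.91, SE 1.04) and the vomeronasal receptor gene Vom2r62 (3.33, SE 1.10). Clec3a was at the ceiling on control replicate 2, which limits the size of its difference, and it was -1.60 from the control mean on injured replicate 1. Or14j3b and Vom2r62 read 7.29 and 7.57 on injured replicate 1, 11.06 and 11.70 on injured replicate 2 and 10.68 and 11.15 on injured replicate 3. The smallest adjusted p belonged to Nrep, at 11.60 ± 0.14 in control and 8.48 ± 0.28 in injured tendon (SD, n = 3), a difference of -3.13 (SE 0.20, adjusted p = 0.141). Gtpbp4, a gene of ribosome assembly, differed by 1.76 (SE 0.14, adjusted p = 0.194).

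**Figure D2:**
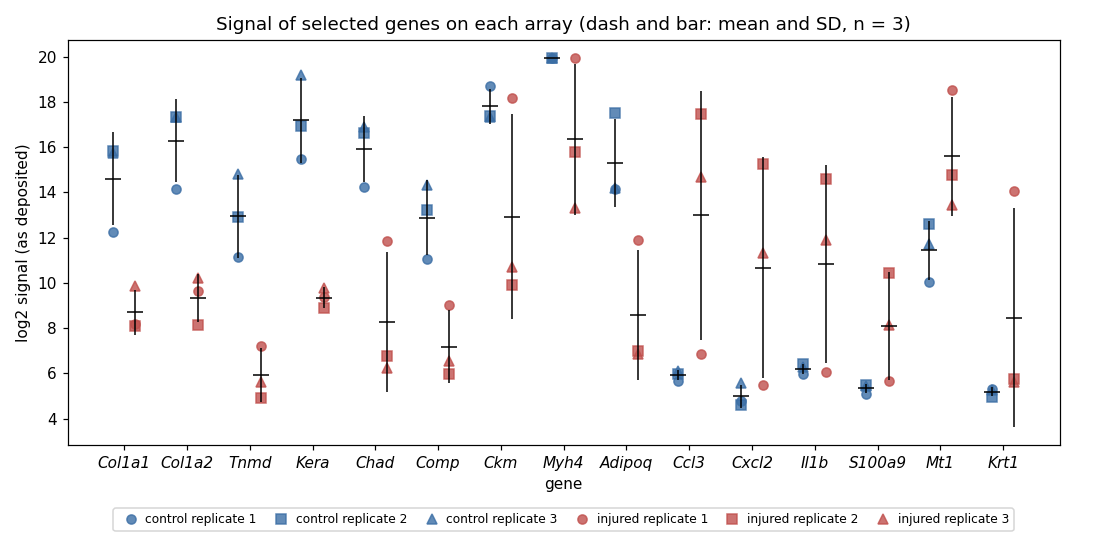
Deposited log2 signal of 15 genes on each of the 6 arrays, with 1 point per array and a dash and bar for the mean and SD of 3 arrays per group. Kera lies between 15.46 and 19.17 on the control arrays and between 8.90 and 9.79 on the injured arrays, whereas Ccl3 reads 6.84 on injured replicate 1 and 17.45 and 14.69 on injured replicates 2 and 3.

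Of 22093 genes tested with limma, 0 passed an adjusted p of 0.05, and 2572 had an unadjusted p under 0.05 (970 higher and 1602 lower in injured tendon), where chance gives 1105. The groups did not overlap for 15.1% of genes, 1567 higher and 1768 lower, where chance gives 10%. The median difference of all genes was 0.15, and it was -0.28 after quantile normalization and -0.38 after centring on array medians, and the medians of lists given here are on the deposited scale and include this shift. Camera called 21 of 32 lists, 4 higher and 17 lower, while camera with an estimated correlation and fry called 0, with smallest adjusted p of 0.359 and 0.105. Without injured replicate 1, 13418 genes passed (8635 higher and 4783 lower), and camera called 19 lists.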

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

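The tests with the X chromosome and with the reference genes were chosen only after the result was seen, and the test with genes of other organs was chosen before it.

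Probe sets without a gene name, which are outside the gene and list comparisons of the report, had a median log2 signal of 6.61 on injured replicate 2 and 6.50 on injured replicate 3. The medians on the control arrays were 5.49, 5.58 and 5.79, and injured replicate 1 was at 5.59. Both values stood out because they lie above the highest control array. Olfactory and vomeronasal receptor genes, 1276 in number, had median differences from the control mean of 2.11 and 2.03 on the same arrays and -0.03 on injured replicate 1.

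Transcription by injured tissue was set against technical explanations of this higher signal. Of 56 genes of liver, brain, eye, pancreas, testis, kidney, thyroid and pituitary, 54 were measured, and their median was 0.85 and 0.755 above the control mean on injured replicates 2 and 3, beyond the range of 0.235 between the control arrays, which argues against transcription by tendon as the source. A shift of the whole array by scaling is argued against by the reference genes, whose median on these arrays was at most -2.11, with a range of 0.26 between the control arrays. That covers only a uniform shift. The SD of the log2 signals over genes was 1.49 and 1.54 on these arrays and 2.03 to 2.25 on the others. A narrower range of signals was not tested as a source. Genomic DNA in the labelled material could raise dim probe sets less on the X chromosome of male rats. The rise there was 0.58 and 0.52 against 0.85 and 0.73 on the autosomes, and 0 of 20 autosomes rose less on either array. However, X minus the lowest autosome was -0.03 on replicate 2 and -0.00333 on replicate 3. The 95% bootstrap intervals were -0.10 to 0.03 and -0.06 to 0.06. On the linear scale the rise on X was 0.50 and 0.55 of that on the autosomes. The same ratio was 0.19, 0.54 and 0.29 on control replicates 1, 2 and 3 and 1.11 on injured replicate 1. The log2 shifts of the autosomes on those arrays were only -0.09, -0.03, 0.13 and -0.01. Ratios of such small shifts are unstable and give no standard for comparison. The sex of the rats is not given. Genomic DNA and unspecific binding cannot be told apart here, and an effect of injury on the material stays open and untested.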

How the results depend on the processing

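The comparison with injured replicate 1 alone, its repeat with an estimated correlation, the covariate for unnamed probe sets and the removal of genes at the ceiling were chosen only after the data were seen. The limma count of 0 genes held under quantile normalization, centring, leaving out dim genes, the mean of probe sets, every probe set tested, eBayes with trend and robust, the covariate and the removal of genes at the ceiling. Unadjusted calls were 970 higher and 1602 lower as deposited, 588 and 2489 after quantile normalization, and 488 and 2525 after centring. Higher calls outnumbered lower ones with trend and robust (1419 and 1308), the replicate block (2457 and 2108), the covariate (1705 and 1012) and every probe set (4638 and 2239). Array quality weights gave 18098 genes (11083 higher and 7015 lower), 7415 of them at least 2-fold, with weights from 0.0531 for injured replicate 1 to 29.0 for injured replicate 3 and an estimate that did not converge. With each array left out in turn, counts ran from 0 to 13418 genes, from 0 to 7354 at least 2-fold and from 19 to 23 lists. Leaving out injured replicate 1 gave the 13418, and each other array left out gave 0. Of 101 genes named or examined, 79 passed without injured replicate 1, 27 higher and 52 lower. With injured replicate 1 alone, 9 genes passed, 9 of them at least 2-fold.

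Camera called 17 to 23 lists under the planned settings other than the tests named next. With an estimated correlation it called 0 lists, and fry called 0. It called 12 lists with injured replicate 1 alone, 0 there with an estimated correlation, and 12 with the covariate. The lists of collagens, collagen enzymes, tendon, matricellular genes, complement and TGF-beta signalling were called under 17 of 20 alternatives, the exceptions being fry and the estimated correlation with all arrays and with injured replicate 1 alone. All 17 used camera at the preset correlation on the same arrays, so they are not independent support. That test called a median of 13 of 32 lists in the simulated unchanged groups. With injured replicate 1 alone, camera reversed the direction of cell cycle (adjusted p = 0.625), pro-inflammatory genes (0.936), endothelium (0.0229), smooth muscle (0.625) and skeletal muscle (0.790), and with an estimated correlation there these adjusted p were 0.987, 0.987, 0.935, 0.987 and 0.987. With the covariate it reversed pro-inflammatory genes (0.988), neutrophil markers (0.966) and endothelium (0.0773). The cause was not tested.

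Whether the replicate numbers pair the arrays could not be told. Deviations of control and injured arrays with the same number correlated at 0.48, -0.04 and 0.59 for numbers 1, 2 and 3. Control replicates 2 and 3 correlated better with another number. Deviations sum to 0 within a group, and injured replicate 1 lay opposite injured replicates 2 and 3, so these correlations neither show nor exclude pairing. With the replicate block, limma gave 0 genes and camera 20 lists, without red blood cell markers (adjusted p = 0.0602). Signals near background limit differences: Cxcl2, Krt1, S100a9, S100a8 and Top2a read below the median unnamed probe set on all 3 control arrays and Tnmd, Cd4, Cd79a and Sp7 on 2 injured arrays, and ceilings limit Dcn, Acta1, Myh4, Clec3a and Gapdh.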

Other observations

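The comparison of the control arrays with injured replicate 1 alone, the tests of a wrong or swapped label, the tests of overall RNA signal and the split of arrays by genes were chosen only after the results were seen.

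Injured replicate 1 carried genes of the epidermis, among others. Against the 3 control arrays, with the spread of the controls assumed for this lone array, limma called 9 genes, all higher: Krt1, Dsp, Dsc3, Calml5, Serpinb5, Pof1b, Arg2, Ampd3 and Slc7a8. Krt1 differed by 8.85 (adjusted p = 0.0437), Dsp, which encodes desmoplakin, by 4.36 (adjusted p = 0.0438), and Dsc3, which encodes a desmosomal cadherin, by 3.92 (adjusted p = 0.0438). Dsp read 6.09 and 5.91 on injured replicates 2 and 3 and between 5.47 and 5.58 on the control arrays. Ampd3, Arg2 and Slc7a8, which are not taken here as genes of the epidermis, differed by 6.19, 5.90 and 4.90. The keratinocyte list had a median of 1.14 on injured replicate 1 (camera adjusted p = 4.59e-14; adjusted p = 0.913 with an estimated correlation). Skin in the piece taken is a candidate source on this array, which was not tested beyond this list.

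The tendon and collagen lists were also called lower with injured replicate 1 alone at the preset correlation and not at an estimated one. There the tendon list had a median of -1.94 (camera adjusted p = 2.84e-10), the collagen list of -1.43 (1.10e-11), the matricellular list of -1.65 (1.54e-06) and the macrophage list of -0.72 (1.03e-04). With an estimated correlation the adjusted p of each of these lists was 0.913, and 0 of 32 lists were called. The preset correlation called 12 lists here, and in the simulated unchanged groups of 3 against 3 it called a median of 13.

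Injured replicate 1 lay close to the control arrays in overall correlation. A control tendon labelled injured cannot be told apart from an injured one, because the tendon list on this array was -1.07 from the lowest control array, inside the range of 1.35 between the control arrays, although 15 of 17 tendon genes were below the lowest control array. A swap with control replicate 1 stays open as well. It lay 1.07 above injured replicate 1 in the tendon list, inside the same range, which is the same gap and no second test. The tendon list was at 0.23 and 0.48 on control replicates 2 and 3 and at -1.94 on injured replicate 1, gaps beyond that range. By this measure these values argue against a swap with control replicate 2 or 3. A smaller injury in injured replicate 1 stays open and untested.

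Tendon matrix genes were low on all injured arrays, and a lower RNA signal of the whole array was weighed as the reason. On injured replicate 1 the tendon list lay -1.64 from the reference genes, both taken against the control mean, beyond the range of 1.35 between the control arrays. On control replicate 1 the tendon list was itself at -0.87 and the reference genes at -0.08. Measured from that lowest control array, as in the label tests, injured replicate 1 lies inside the range, so this test does not settle the question there. On injured replicates 2 and 3 the gap between tendon list and reference genes was at most -0.74, inside that range. A lower RNA signal thus cannot be told apart from lower matrix expression on those arrays. More muscle and less tendon in the piece taken from injured replicate 1 cannot be told apart either, since muscle genes below the ceiling had a median of 0.0183 there, with a range of 1.19 between the control arrays. An effect of injury on tenocytes may account for the low matrix genes and stays open, as a hypothesis that these arrays do not separate from the others.

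The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. With limma, 10 of the 10 splits gave as many genes as the real one, which gave 0, and the highest other gave 0, a comparison that a count of 0 fixes in advance and that says nothing about chance. At an unadjusted p under 0.05 the real split gave 2572 genes and the highest other 9835, with control replicates 1 and 2 and injured replicate 1 on one side, which points to a structure of the samples apart from the groups. For gene lists, 1 of the 10 splits gave as many as the real one, which gave 21, and the highest other gave 19.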
